A study of Homo sapiens with 4 samples.

How the data were processed

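The samples were 4 RNA-seq libraries of MOLM-13 cells, 2 untreated and 2 treated with doxycycline for 4 days to overexpress GADD45G. Groups were taken from the treatment labels and titles, and replicate numbers from the presence of a suffix in the titles. Per the labels' protocols, total RNA was extracted with a column kit and libraries followed standard Illumina protocols; strand, read length and RNA selection are not given in the sources used here.

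Per the file headers, the deposited values are RPKM, 1 value per Ensembl gene ID and library. The submitters' processing notes name TopHat, Cuffnorm, Cuffdiff and the build hg19, without versions or roles. In each library 100.0% of the low values checked (up to 20 reads) were whole multiples of the value of 1 read, within 0.01 reads, for IDs with an identical gene model in GENCODE release 29. The authors' RPKM values therefore follow from whole reads, the summed exon length of a gene and a library depth, and the depth of each library could be recovered: 18778791, 15683931, 18895470 and 15968886 reads for untreated controls 1 and 2 and induced replicates 1 and 2. For 98.4% of the 10818 tested IDs the reads of each library were recovered, with lengths taken from identical models (1120 IDs) or solved from the values (9521 IDs, with the length nearest to that of the reference gene where several fitted). For both, the values above 0 had to be whole within 0.005 reads, slightly more at high counts. A single read in a gene of 1 kb was worth 0.0533, 0.0638, 0.0529 and 0.0626 RPKM, and a count of 0 reads allows up to 3 reads. Exact Poisson intervals of 95% were computed for a few genes; intervals and floors cover counting error only. Reads in overlapping genes were counted in each gene, so antisense and host genes cannot be told apart by their reads. Gene families with near-identical copies are uncertain.

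The complete files list 57820 IDs. The file of induced replicate 1, as used here, ends within a row after 27332 IDs, and genes were tested only where all 4 files list them. These hold 93.3% of the protein-coding IDs (17965 of 19263) and 86.8%, 85.5% and 86.3% of the RPKM total of controls 1 and 2 and induced replicate 2. Of the 57820 IDs, 51996 were paired with a symbol through a table of gene names. No coordinates are given, because the reference used for names is of another build than the files. Whether the expressed construct holds the whole GADD45G transcript is not given in the sources used here, so its RPKM is relative to the length of the endogenous gene.

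Rows of 1 symbol were summed. Genes with a mean of at least 1 RPKM over the 4 libraries were kept (10771), log2(RPKM + 1) was computed with no further scaling, and limma (version 3.58.1, R 4.3.3; lmFit, then eBayes with trend) compared induced with untreated libraries, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The residual degrees of freedom were 2 and the prior degrees of freedom 8.72. Group levels, SDs and folds of group means were computed on the RPKM values with pandas 2.3.3 and numpy 2.4.6. Gene lists were fixed before the data were examined, as were the design, the alternatives and the rule for named genes. Of 810 different genes in 37 lists, 788 were matched to the files and 620 were tested. Lists with at least 3 tested members were tested with camera at a correlation of 0.01, two-sided, with adjustment over 36 lists; beside it stand camera with an estimated correlation, camera on ranks and fry. Counts of members are given over all genes and adjusted over the list alone.

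Named genes are GADD45G, GADD45A and GADD45B; the 15 largest increases and 15 largest decreases in log2(RPKM + 1) among called genes whose induced values both lay above or below both controls, leaving out small RNA genes, unnamed loci and pseudogenes; and up to 4 tested members of each list with the smallest adjusted p. The rule gave 154 genes, of which the text describes a part; some genes are not reported here.

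The fit was tested on simulated values for the 10771 genes, in 5 runs with 100 genes changed at each size. Values were independent and normal, with spreads drawn from the prior that the fit had estimated. Of genes with a log2 change of 1, 30.4% were recovered, and of those with a change of 2, 98.6%, while 4.9% of calls were false. The simulation follows the fit's own assumptions and changed far fewer genes than were called in the data. These rates therefore check the code and do not carry over to the real comparison. Alternatives were other pseudocounts (0.1 and 5), no filter and a filter at 5 RPKM, upper quartile, TMM and quantile scaling, eBayes without trend and with a robust prior, a replicate block, each library left out, small RNA genes left out, the highest row per symbol, and genes with missing values kept. Added after seeing the data were limma's voom on the recovered reads, a shift of the median change to 0, and leaving out genes seen in both replicate 1 libraries alone. Count models were planned for recovered counts and were not run, because the unit of the files is RPKM.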

Results

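Messenger and other RNA was profiled by sequencing in MOLM-13, an established human acute myeloid leukaemia line that carries an internal tandem duplication of FLT3 and an MLL-AF9 fusion. Cells were left untreated or received doxycycline (1 mg/ml, as labelled) for 4 days to overexpress GADD45G, a stress-inducible protein of the growth arrest and DNA damage family that binds the kinase MAP3K4 upstream of p38 and JNK. Each group held 2 libraries, which the design text describes as biological replicate experiments. The untreated libraries had 18778791 and 15683931 reads and the induced libraries 18895470 and 15968886 reads, as recovered from the values. Doxycycline and the expressed gene differed together between the groups, and doxycycline-treated cells without the construct were not analysed here, so every difference reported covers both. Levels are RPKM, reads scaled to gene length and library depth, given as mean ± SD with n = 2 per group. Changes are on the log2(RPKM + 1) scale, which understates those of low genes.

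GADD45G (ENSG00000130222), the gene to be induced, stood at 3236 and 2118 RPKM in the induced libraries against 10.5 and 0.289 RPKM in the untreated ones. Its log2 change was 9.41 ± 0.73 (SE; limma, adjusted p = 9.74e-06). The control values came from 261 reads (95% counting interval 9.28 to 11.9 RPKM) and 6 reads (0.106 to 0.630 RPKM), so the controls differed from each other by more than counting error. Without untreated control 1 the log2 change was 10.99, and without untreated control 2 it was 7.83. Of the related genes, GADD45B fell from 19.0 ± 1.08 to 7.06 ± 0.62 RPKM (log2 change -1.31, adjusted p = 0.000906). GADD45A was at 3.84 ± 1.12 RPKM in the controls and 7.34 ± 3.19 RPKM after induction, a difference that did not pass the threshold (limma adjusted p = 0.0627). The difference passed after upper quartile, TMM and quantile scaling and a shift of the median change to 0. It also passed with a filter at 5 RPKM, a robust prior, small RNA genes left out and voom (adjusted p of these settings 0.0191 to 0.0360). With a replicate block that pairs libraries by suffix it passed as well (0.00569). The log2 change of GADD45A was 0.75 with all libraries, 1.15 without GADD45g induced 2 and 0.35 without GADD45g induced 1. The plot of RPKM per library shows these genes with others named in the comparison.

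**Figure D1:**
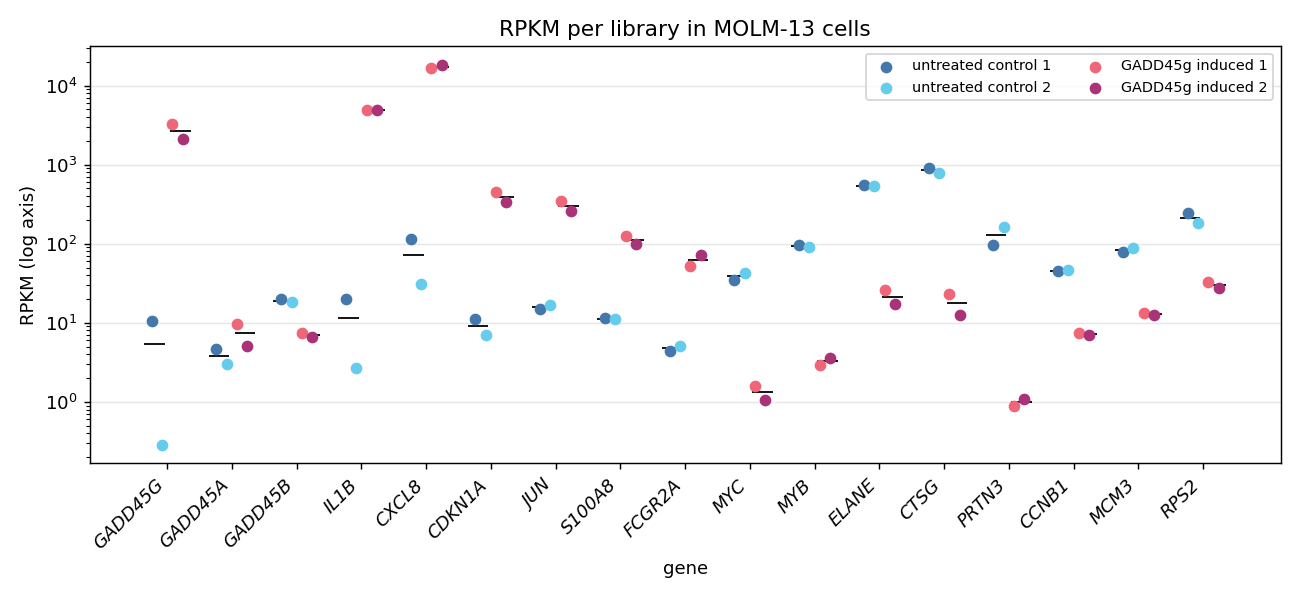
Levels of 17 genes in RPKM (log axis) in each of the 4 libraries, as 1 point per library, with a black line at the mean of each group of 2. GADD45G reached 3236 and 2118 RPKM after induction, and IL1B, CXCL8 and CDKN1A lay above both controls, while MYC, MYB, ELANE, CTSG and PRTN3 lay below both controls.

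The largest increases after induction included genes of secreted inflammatory and matrix proteins. CXCL8, the neutrophil chemokine interleukin-8, went from 72.7 ± 58.6 to 17250 ± 1112 RPKM (log2 change 8.14 ± 0.48, adjusted p = 1.46e-06). IL1B, the cytokine interleukin-1 beta, rose from 20.2 and 2.72 RPKM in the controls to 4868 and 4855 RPKM (log2 change 9.10 ± 0.60, adjusted p = 2.90e-06). The 15 largest increases under the naming rule also took in the growth factor subunit INHBA (log2 change 7.67), the platelet chemokine PPBP (7.53), the interstitial collagenase MMP1 (6.76) and the immediate early gene IER3 (6.75). CXCL2, a chemokine, changed by 6.11, SPP1 (osteopontin) by 6.05 and the ERK phosphatase DUSP5 by 5.79. SERPINB2, an inhibitor of plasminogen activators, went from 71.6 ± 24.9 to 3760 ± 337 RPKM. The remaining increases were THBD (thrombomodulin, 5.52), RGS1 (5.41), CDKN1A (5.30) and the cytokine LIF (5.08). Several of these genes were higher in untreated control 1 than in untreated control 2, as GADD45G was. INHBA stood at 1.19 and 0.0762 RPKM, PPBP at 1.19 and 0.0892 RPKM and CXCL8 at 114 and 31.3 RPKM.

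The largest decreases included granule proteases of immature myeloid cells and regulators of proliferation. PRTN3 (proteinase 3) fell from 129 ± 47.8 to 0.988 ± 0.153 RPKM (log2 change -5.99 ± 0.27, adjusted p = 2.83e-07) and CTSG (cathepsin G) from 846 ± 99.0 to 17.7 ± 7.43 RPKM (log2 change -5.55 ± 0.31). ELANE, neutrophil elastase, was 25.0-fold lower after induction and AZU1 (azurocidin) 20.5-fold lower. MYB, a transcription factor that MLL-fusion leukaemias depend on, fell from 93.5 ± 2.67 to 3.28 ± 0.48 RPKM (adjusted p = 5.46e-07). MYC fell from 39.0 ± 5.51 to 1.33 ± 0.37 RPKM (adjusted p = 1.05e-06). DEFB1 (log2 change -4.30), GPR153 (-3.55), the spermidine synthase SRM (-3.47), the eosinophil ribonuclease RNASE3 (-3.47), HTRA4 (-3.41), the nucleolar protein NOLC1 (-3.31), LY86 (-3.23), METAP1D (-3.17) and the mitochondrial folate enzyme MTHFD1L (-3.05) made up the rest of the 15 largest decreases.

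Over 10771 tested genes, limma called 4185 at an adjusted p under 0.05, of which 1314 were higher and 2871 lower after induction. The median log2 change of the tested genes was -0.21. After TMM scaling of the RPKM values, which moved that median by 0.23, the calls were 1967 higher and 2021 lower; after quantile normalization they were 1874 and 2080, and after upper quartile scaling 1700 and 2293. The excess of lower calls therefore depended on the scaling, and changes are best read against the median of -0.21. Genes called higher held 7.5% and 7.9% of the reads recovered for tested genes in the controls and 29.7% and 30.1% after induction. The direction of that difference follows from how these genes were chosen. Its size was measured in the same libraries that chose them, and so also depends on that choice. At a log2 change of at least 1, 732 genes were higher and 1692 lower. Without GADD45g induced 1 the count of calls was 2719, and without GADD45g induced 2 it was 2597. The calls included 59 small RNA genes, 95 unnamed loci and 38 pseudogenes, which are only counted. Induced and control values did not overlap for 7536 of the 10771 tested genes, where chance gives 33.3% of genes for libraries on a common scale. The values were not rescaled for this count, so the shift of the median change to -0.21 can add to it.

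**Figure D2:**
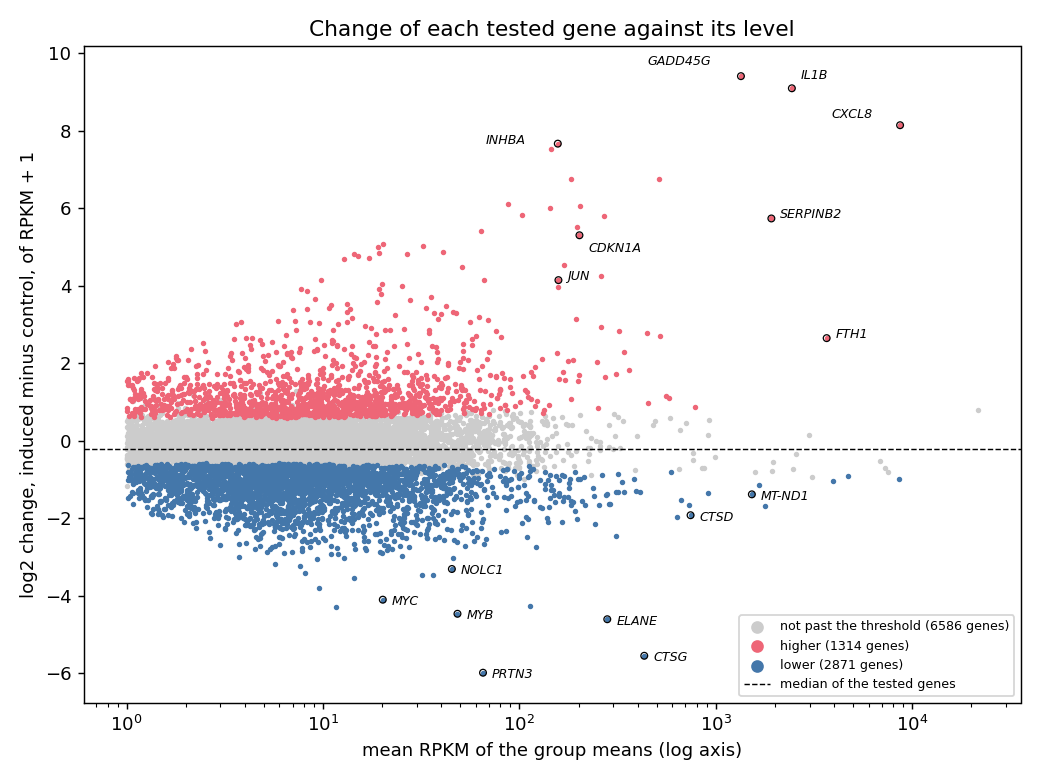
Log2 change (induced minus control, of RPKM + 1) of each tested gene against its mean RPKM (log axis), 1 point per gene, with genes past the threshold in colour (1314 higher, 2871 lower) and the dashed line at the median change of -0.21. GADD45G, IL1B and CXCL8 lie at the top and PRTN3 and CTSG at the bottom.

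Libraries of the same group resembled each other more than those of different groups. Across the tested genes, which are not independent replicates, Pearson's r of log2(RPKM + 1) was 0.957 between the controls and 0.971 between the induced libraries, against 0.796 to 0.815 between groups. The SD of the log2 difference was 0.45 and 0.38 within groups and 0.95 to 0.99 between them. The titles of control 2 and induced 2 carry the same suffix. Epithelial markers set control 1 and induced 1 apart from the other libraries. KRT8 was at 13.2 RPKM in control 1 and 13.9 RPKM in induced 1, but at 0 and 0.0375 RPKM in control 2 and induced 2. KRT19 had 526 and 473 reads against 0 and 0 reads, which allow up to 0.0819 and 0.0804 RPKM. EPCAM was at 5.75 and 5.82 RPKM against 0 and 0. Of the 6 tested members of the fibroblast and epithelial list, 0 passed the threshold over all genes or adjusted over the list alone. FAP and TAGLN were the 2 with an unadjusted limma p under 0.05. FAP was at 2.43 ± 0.75 RPKM in the controls and 4.18 ± 0.12 RPKM after induction. It passed after upper quartile, TMM and quantile scaling, a shift of the median change to 0, a robust prior, small RNA genes left out and voom (adjusted p = 0.0138 to 0.0382). Its call also changed with the replicate block (0.0227) and without untreated control 1. TAGLN, at 1.26 ± 0.19 and 2.18 ± 0.07 RPKM, passed after TMM and quantile scaling and the shift of the median. As a list the tested members did not pass with camera (adjusted p = 0.281). The call changed to higher without untreated control 1 and without GADD45g induced 2. Either omission leaves the epithelial signal unbalanced between the groups, which by itself raises KRT8 and KRT19. These calls therefore cannot show an induced change.

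Genes of cell division and DNA replication fell almost without exception. In the G2/M list 29 of 30 tested members fell over all genes and 30 adjusted over the list alone, with a median log2 change of -2.02 (camera adjusted p = 5.42e-14; adjusted p = 0.273 with an estimated correlation). Cyclin A2 (CCNA2) went from 37.8 ± 7.18 to 4.90 ± 0.59 RPKM, cyclin B1 (CCNB1) from 45.7 ± 0.46 to 7.22 ± 0.41 RPKM, and the spindle checkpoint kinase BUB1B was 7.27-fold lower. In the S phase and E2F list all 28 tested members fell, both over all genes and adjusted over the list alone, with a median of -1.81 (camera adjusted p = 7.75e-12; adjusted p = 0.200 with an estimated correlation). The replicative helicase subunits MCM4, MCM3 and MCM2 were 7.08-fold, 6.52-fold and 6.07-fold lower. Of 30 tested DNA damage response and repair genes, 21 fell and 1 rose over all genes, and 22 fell and 1 rose adjusted over the list alone (median -0.78; camera adjusted p = 0.000137; adjusted p = 0.547 with an estimated correlation). PARP1, which binds DNA breaks, was 4.64-fold lower and the clamp PCNA was 3.40-fold lower; PCNA is also a replication gene and stands in both lists.

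Ribosome production genes fell along with MYC. Of 24 tested members of the list of MYC targets and ribosome biogenesis, 22 fell over all genes and 23 adjusted over the list alone (median -2.03; camera adjusted p = 3.85e-11; adjusted p = 0.200 with an estimated correlation). NOLC1 went from 83.1 ± 7.23 to 7.46 ± 0.12 RPKM and the ribosome assembly factor RRS1 was 13.8-fold lower. Among 29 tested cytosolic ribosomal protein genes 27 fell over all genes and 28 adjusted over the list alone (median -1.32; camera adjusted p = 4.50e-07; adjusted p = 0.452 with an estimated correlation). RPS2 fell from 213 ± 44.4 to 30.5 ± 3.67 RPKM, RPL4 from 279 ± 35.2 to 87.0 ± 9.66 RPKM and RPLP0 from 281 ± 23.2 to 94.1 ± 17.6 RPKM. Ribosomal protein genes have many processed pseudogenes, so their levels depend on how shared reads were assigned.

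Some inhibitors of the cell cycle rose. CDKN1A, which encodes the CDK inhibitor p21, went from 9.17 ± 3.03 to 395 ± 76.8 RPKM (log2 change 5.30 ± 0.28, adjusted p = 6.95e-07), and CDKN2B, which encodes p15, from 0.949 ± 0.142 to 20.5 ± 6.46 RPKM. BTG1, an antiproliferative gene, was 4.41-fold higher. In the list of CDK inhibitors and growth arrest 6 of 16 tested members rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.00484; 0.0582 without untreated control 2 and 0.0826 with no filter; adjusted p = 0.547 with an estimated correlation). Of 22 tested p53 target genes 6 rose and 3 fell over all genes, and 7 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0179; 0.0572 to 0.0787 on ranks, with fry, with no filter and without untreated control 2; adjusted p = 0.549 with an estimated correlation). Besides CDKN1A, the stress cytokine GDF15 rose from 5.51 and 1.99 RPKM in the controls to 54.6 and 30.4 RPKM and PLK3 was 6.59-fold higher, while CCNG1 (cyclin G1) was 4.32-fold lower. Among 29 tested apoptosis genes 9 rose and 4 fell, over all genes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0802), but did so without untreated control 1 (0.0435) and with a filter at 5 RPKM (0.0271). The BH3-only gene PMAIP1 (NOXA) rose from 10.2 and 4.08 RPKM in the controls to 83.9 and 60.5 RPKM, BMF, another of this class, was 3.87-fold higher, and the inhibitor BIRC5 (survivin), also a G2/M gene, was 6.16-fold lower.

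Many inflammatory and immediate early genes rose. Of 22 tested NF-kB and inflammatory genes 16 rose and 0 fell over all genes, and 17 rose adjusted over the list alone (median 0.93; camera adjusted p = 7.75e-12; adjusted p = 0.200 with an estimated correlation). Beside CXCL8, IL1B and CXCL2, the cytokine IL1A rose from 0.215 ± 0.050 to 37.8 ± 4.53 RPKM, and PTGS2, the inducible cyclooxygenase, from 0.647 and 0.0605 RPKM in the controls to 33.4 and 34.4 RPKM. Of 23 tested AP-1 and immediate early genes 17 rose and 1 fell over all genes, and 18 rose and 1 fell adjusted over the list alone (median 1.54; camera adjusted p = 5.80e-12; adjusted p = 0.473 with an estimated correlation). JUN, an AP-1 subunit and substrate of JNK, went from 15.9 ± 1.15 to 300.0 ± 59.7 RPKM (log2 change 4.14 ± 0.25, adjusted p = 1.68e-06), ATF3 was 16.6-fold higher, and IER3 went from 14.96 and 4.09 RPKM in the controls to 1325 and 704 RPKM. In the list of p38 and JNK pathway kinases and phosphatases 5 of 18 tested members rose and 2 fell, over all genes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.286). The members with the smallest adjusted p were all phosphatases that switch these kinases off: DUSP1 rose from 1.00 and 2.15 RPKM in the controls to 43.1 and 31.1 RPKM, DUSP8 by 2.08 on the log2 scale, and DUSP16 and DUSP10 were 2.65-fold and 2.60-fold higher.

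Myeloid genes moved in opposite directions. In the monocyte and macrophage list 10 of 21 tested members rose and 3 fell over all genes, and 10 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.00420, 0.0572 on ranks; adjusted p = 0.431 with an estimated correlation). The Fc receptor gene FCGR2A went from 4.79 ± 0.49 to 62.1 ± 12.9 RPKM and the calgranulin S100A12 from 0.310 and 0.989 RPKM in the controls to 16.1 and 15.8 RPKM, and the calgranulin S100A8 was 10.0-fold higher, while IRF8, a transcription factor of the monocyte lineage, was 8.08-fold lower. In the granulocyte list 7 of 10 tested members fell and 2 rose, over all genes and adjusted over the list alone (median -2.59; camera adjusted p = 0.00470, 0.0637 with no filter on low values; adjusted p = 0.547 with an estimated correlation), led by PRTN3, CTSG, ELANE and AZU1. Of 7 tested stem and progenitor markers 3 fell and 1 rose, over all genes and adjusted over the list alone, without passing as a list (camera adjusted p = 0.332); LMO2 was 11.4-fold lower and the integrin ITGA4 4.47-fold lower. In the MLL-AF9 and HOX list 3 of 16 tested members fell and 2 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.995), with MYB lower and RUNX2 3.69-fold higher. The HOXA9 and MEIS1 log2 changes were -0.43 and -0.41 and did not pass, names chosen after their values were seen.

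**Figure D3:**
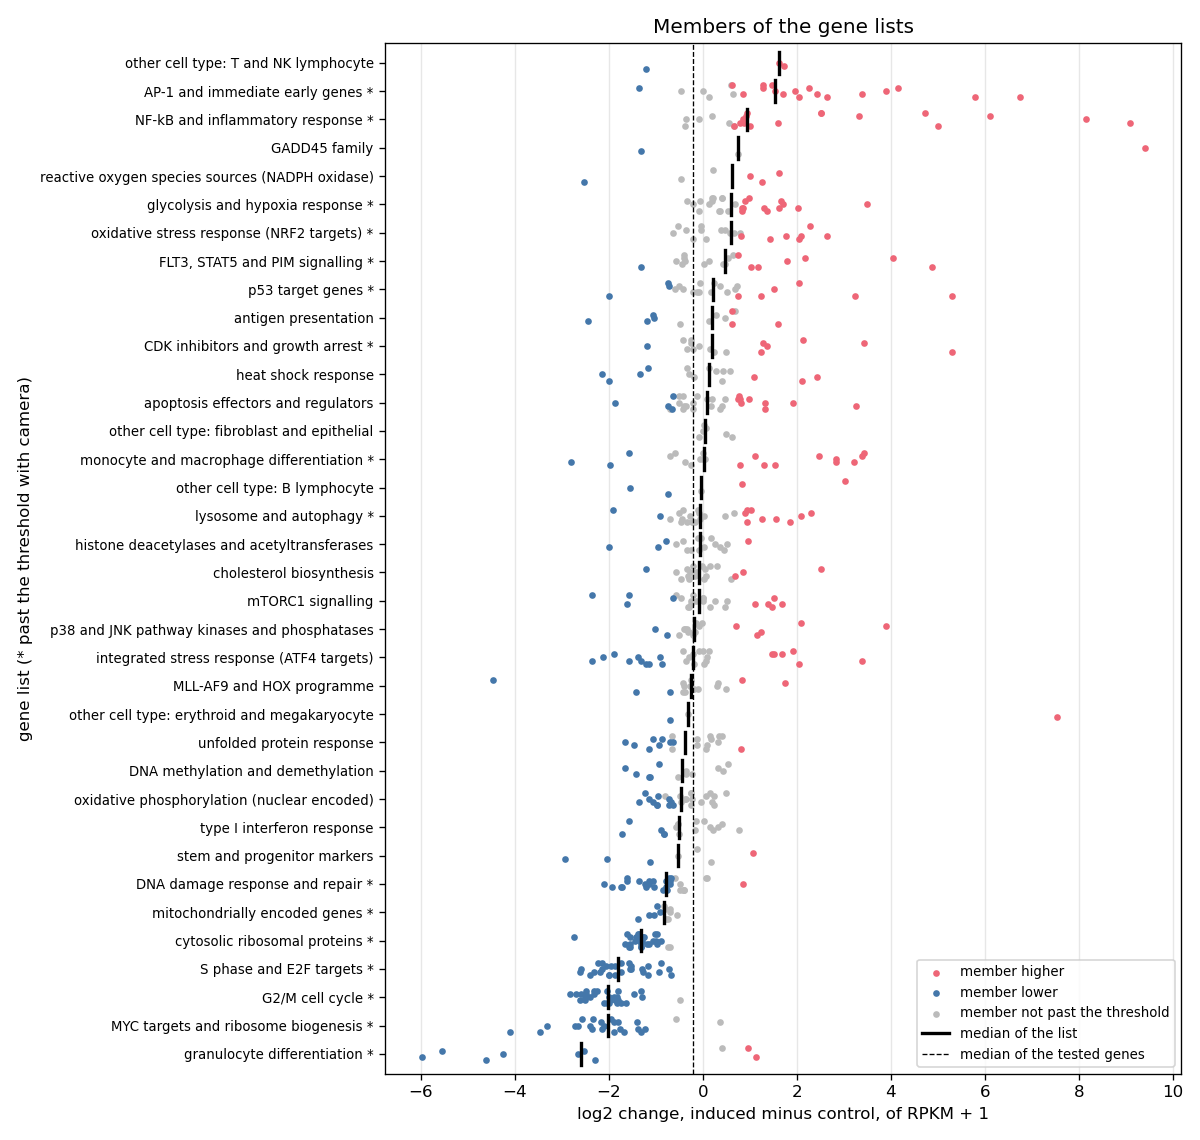
Log2 change (induced minus control, of RPKM + 1) of the tested members of 36 gene lists, 1 point per gene, with members past the threshold in colour, a black line at the median of each list and a dashed line at the median of the tested genes (-0.21). The G2/M, S phase and MYC target lists lie almost wholly to the left, with medians of -2.02, -1.81 and -2.03, and the AP-1 and NF-kB lists mostly to the right, with medians of 1.54 and 0.93.

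Some genes of cytokine and kinase signalling changed. In the FLT3, STAT5 and PIM list 7 of 19 tested members rose and 1 fell over all genes, and 8 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.00293, 0.0702 with fry; adjusted p = 0.547 with an estimated correlation). The cytokine OSM went from 1.74 ± 0.14 to 79.6 ± 11.6 RPKM and PHLDA1 from 2.53 and 0.616 RPKM in the controls to 43.0 and 34.0 RPKM, and the cytokine signalling inhibitor SOCS3 and the kinase PIM1 were 10.6-fold and 3.50-fold higher. In the mTORC1 list 5 of 24 tested members rose and 4 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.332). SESN2 and DDIT4 were 3.48-fold and 3.29-fold higher, while the amino acid transporter SLC7A5 was 6.21-fold lower and DEPTOR 9.38-fold lower.

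Stress and metabolic lists changed in part. Among 19 tested NRF2 targets of the oxidative stress response 7 rose and 0 fell over all genes, and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000275; adjusted p = 0.357 with an estimated correlation). Thioredoxin reductase TXNRD1 went from 53.2 ± 10.8 to 259 ± 8.98 RPKM, and the autophagy receptor SQSTM1 and the cystine transporter SLC7A11 were 4.35-fold and 4.11-fold higher. Of 26 tested glycolysis and hypoxia genes 12 rose and 0 fell, over all genes and adjusted over the list alone (median 0.60; camera adjusted p = 7.26e-07; adjusted p = 0.520 with an estimated correlation). ADM, which encodes adrenomedullin, was 13.1-fold higher, NDRG1 4.12-fold and VEGFA 3.33-fold. In the lysosome and autophagy list 9 of 26 tested members rose and 2 fell, over all genes and adjusted over the list alone. Its median was -0.07 while its mean was 0.28 and its test pointed higher (camera adjusted p = 0.0349, and 0.0530 to 0.163 with fry, on ranks, after quantile normalization, with no filter and without untreated control 2; adjusted p = 0.473 with an estimated correlation); with the other scalings tried the median was above 0. The protease cathepsin B (CTSB) was 4.91-fold higher and cathepsin D (CTSD) 3.83-fold lower.

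Some mitochondrial transcripts fell. Of 12 tested mitochondrially encoded genes 5 fell and 0 rose, over all genes and adjusted over the list alone (median -0.82; camera adjusted p = 0.0485; adjusted p = 0.533 with an estimated correlation), and MT-ND1 went from 2201 ± 69.9 to 848 ± 140 RPKM. Without untreated control 1, untreated control 2 or GADD45g induced 1 the adjusted p of this list was 0.0729, 0.163 and 0.165, and the call also ended with no filter, a filter at 5 RPKM, small RNA genes left out, voom and the shared genes of replicate 1 libraries left out (0.0516 to 0.224). Mitochondrially encoded genes held 6.9% and 7.1% of the recovered reads in the controls and 3.9% and 4.3% after induction. Of 27 tested nuclear genes of oxidative phosphorylation 11 fell and 0 rose, over all genes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.171, 0.00346 with no filter); the complex III subunit UQCRFS1 was 2.67-fold lower. In the ATF4 target list of the integrated stress response 6 of 27 tested members rose and 10 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.995). ATF3 and CEBPB rose, whereas SLC7A5 and PHGDH, an enzyme of serine synthesis, were 6.21-fold and 4.56-fold lower.

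In total 16 of 36 lists passed with camera at a preset correlation, 9 higher and 7 lower, and 0 passed with an estimated correlation, where 5 had an unadjusted p under 0.05; fry called 19 lists, which tests each list on its own rather than against other genes. Among the remaining lists that did not pass with camera, the unfolded protein response had 8 lower and 1 higher of 20 tested members (adjusted p = 0.495) and 10 lower and 1 higher adjusted over the list alone, with the chaperone-like isomerase PDIA4 2.83-fold lower. The heat shock list had 3 higher and 4 lower of 15 (adjusted p = 0.375), with the inducible HSPA1B 5.93-fold and its near-identical copy HSPA1A 4.77-fold higher and the constitutive HSPA8 4.45-fold lower. In the NADPH oxidase list 3 of 6 rose and 1 fell (adjusted p = 0.242); the catalytic subunit CYBB was 6.69-fold lower. Among 20 tested cholesterol genes 3 rose and 1 fell over all genes, and 1 and 1 adjusted over the list alone (adjusted p = 0.347), with SQLE 5.92-fold higher. Type I interferon genes had 5 lower of 17 (adjusted p = 0.427), with LY6E 3.51-fold and USP18 11.4-fold lower. Antigen presentation genes had 3 higher and 4 lower of 12 (adjusted p = 0.596), with CD74 6.79-fold lower. DNA methylation and demethylation genes had 5 lower of 12 (adjusted p = 0.291, 0.0272 with no filter), led by APOBEC3B, 3.74-fold lower, and histone deacetylases and acetyltransferases 1 higher and 3 lower of 17 (adjusted p = 0.817), led by KAT2A, 4.67-fold lower. Counts were equal adjusted over the list alone for the heat shock, NADPH oxidase, interferon, antigen presentation, DNA methylation and histone modifier lists.

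Markers of other blood lineages were few. The GADD45 family (adjusted p = 0.281), erythroid and megakaryocyte (0.332), T and NK lymphocyte (0.171, and 0.0305 with no filter), B lymphocyte (0.442) and fibroblast and epithelial (0.281) lists did not pass with camera. Of these lists 3, 3, 3, 5 and 6 members were tested. With the replicate block the GADD45 family (1.12e-07) and the erythroid and megakaryocyte list (0.000123) passed, carried by GADD45G and PPBP. The fibroblast and epithelial call changed without untreated control 1 and without GADD45g induced 2, where the epithelial signal is unbalanced between the groups. In the GADD45 family 1 member rose and 1 fell over all genes, and 2 rose and 1 fell adjusted over the list alone. Over all genes and adjusted over the list alone alike, 2 T and NK lymphocyte members rose and 1 fell, and 2 B lymphocyte members rose and 2 fell. PPBP was the erythroid and megakaryocyte member that rose by both counts, and EPOR the one that fell (adjusted p = 0.0341), a call that ended after each scaling tried and with each library left out. FCRLA, a B cell gene, was at 0.0163 and 0 RPKM in the controls and 7.45 and 6.92 RPKM after induction, while the B cell adaptor BLNK fell from 2.79 and 2.62 RPKM to 0.0714 and 0.490 RPKM. NKG7, a granule membrane gene of cytotoxic cells, was 2.32-fold lower, and GZMB rose from 0.303 and 0.951 RPKM in the controls to 4.10 and 4.45 RPKM. Of the 16 genes of the canonical histone list 3 were matched and 2 tested, too few for a list test. H1-2 was 8.50-fold higher, while H1-4 had a log2 change of -0.44 and did not pass (limma adjusted p = 0.268).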

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

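The search of genes listed in 3 of the 4 files was chosen after the file lengths were seen. These genes were left out of the comparison because induced replicate 1 has no value for them as used here, so what follows rests on induced replicate 2 and has no replicate check. Of 3634 named genes of this kind, without small RNA genes and pseudogenes, 7 stood at 5 RPKM or more and at least 10-fold above both controls, and 3 were at least 10-fold lower. TMEM158, a membrane protein gene, was at 58.3 RPKM (1689 reads) against 3.14 and 2.22 RPKM in the controls. MGAM, which encodes maltase-glucoamylase, was at 50.1 RPKM (8612 reads) against 4.01 and 4.75 RPKM. The other 5 are antisense genes, including IER3-AS1 (366 RPKM), PHLDA1-AS1 (102 RPKM) and LUCAT1 (17.7 RPKM); IER3 and PHLDA1 themselves rose, and without strand their reads cannot be assigned to either partner. Among the lower genes, LILRA2 was at 1.79 RPKM against 35.7 and 44.3 RPKM.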

How the results depend on the processing

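The replicate block, the scalings and the other settings were planned, except voom, the shift of the median and the removal of genes shared by replicate 1 libraries, which were chosen after seeing the data. GADD45G stayed past the threshold in all 20 alternatives, with log2 changes of 7.83 to 10.99 over the libraries left out. It did so narrowly with a robust prior (limma adjusted p = 0.04745) and with no filter (0.0232), against 9.74e-06 in the planned fit. The count of changed genes (4185; 1314 higher, 2871 lower) was 2462 with no filter (823 higher, 1639 lower), where more low genes were tested and the prior degrees of freedom fell to 2.16, and 2424 at a log2 change of at least 1 (732 higher, 1692 lower). Leaving out 1 library each, with the lone library of a group assumed to vary like the others, gave 2597 to 3582 calls (798 to 1133 higher, 1766 to 2449 lower). In the remaining alternatives it was 3084 to 4987. No gene called in both changed direction in any setting. Of the 16 lists, 0 passed with an estimated correlation (lowest camera adjusted p 0.200), and this estimate rests on 2 residual degrees of freedom. The lists at 0.200 were those of S phase, MYC targets and NF-kB. Their estimated correlations (-0.013, -0.015 and -0.044) were below the preset 0.01, so a larger correlation did not end these calls. In some other lists the estimate was above 0.01, as for AP-1 (0.377), and the cause was not tested for the other lists. The other alternatives passed 12 to 19 lists. Lists that passed with fry and not with camera were those of stem and progenitor markers, type I interferon, DNA methylation, erythroid and megakaryocyte, T and NK lymphocyte and B lymphocyte genes (fry adjusted p = 0.0182 to 0.0394). These fry calls do not set a list against the median change of -0.21 of the tested genes. Of 3 tested erythroid and megakaryocyte members only PPBP rose, and of 5 tested B lymphocyte members 2 rose and 2 fell. Of 147 genes taken by the naming rule and past the threshold 119 kept their call wherever they were tested and 0 reversed; all 30 with the largest changes kept theirs. FTH1, MT-ND1, RAC2 and DNMT1 were among those that lost theirs with no filter. The labels do not say what the suffixes mark, but same-suffix libraries shared signal. Deviations from the group means correlated at r = 0.35 between them (0.31 without the genes shared by replicate 1 libraries). The fit with the replicate block called 4987 genes and 18 lists (11 higher, 7 lower). It had 1 residual degree of freedom and infinite prior degrees of freedom, so each gene took its variance from the fitted trend. The lists that the block added were the GADD45 family (camera adjusted p = 1.12e-07) and the erythroid and megakaryocyte list (0.000123), with 3 tested members each. The first holds the induced gene GADD45G itself (log2 change 9.41), beside GADD45A (0.75) and GADD45B (-1.31). In the second PPBP changed by 7.53, EPOR by -0.69 and GP1BA by -0.31. Each result rests on 1 gene, so neither describes a family or lineage. Of the genes taken by the naming rule, GADD45A (adjusted p = 0.00569) and FAP (0.0227) passed with the block and did not pass in the planned fit without it, though some other settings also called them, and the block changed no other call among the lists and these genes. Missing values were not run for the lists, nor count models for any result. In a gene of 1 kb, 3 reads are worth 0.159 to 0.191 RPKM.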

Other observations

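Families defined by the start of their symbols were chosen after the gene values were seen, so only counts are given for them and no test. Of 9 tested matrix metalloproteinase genes 7 rose and 1 fell (median log2 change 1.54). MMP14, a membrane-bound activator of other proteases, changed by 4.81, the stromelysin MMP10 by 3.93 and MMP19 by 2.35. Of 6 tested CXC chemokine genes 5 rose, among them CXCL5 (4.69), CXCL6 (3.87) and CXCL3 (2.52). Over 7 tested serpins 3 rose and 3 fell, and SERPINB1, an inhibitor of neutrophil proteases, changed by -2.26. The aldo-keto reductases AKR1C1, AKR1C3 and AKR1C4 changed by 4.15, 1.16 and 1.88, with reads that near-identical copies can share.

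Several other families chosen in this way had more members lower than higher, as had all 10771 tested genes (2871 lower, 1314 higher). Of 18 tested subunits of RNA polymerases I and III 12 fell and 0 rose (median -0.89), of 66 mitochondrial ribosomal protein genes 36 fell and 2 rose (median -0.72), and of 38 translation initiation factor genes (groups 2 to 5) 20 fell and 1 rose (median -0.73). MRPL24 changed by -2.32, while MRPL52 went the other way by 2.29. Of 17 aminoacyl-tRNA synthetases 9 fell, led by LARS1 at -2.19, and of 21 nucleoporins 13 fell, led by NUP210 at -2.56, with 0 members that rose in either. The medians of these 5 families stayed below 0 after TMM, quantile and upper quartile scaling, whereas that of 33 proteasome subunits was -0.13 as deposited and 0.12 after TMM scaling, with 3 members lower.

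The tests of the shared epithelial signal and of carry-over were chosen after the values were seen. A set of 28 named genes stood at 1 RPKM or more in untreated control 1 and induced 1 and at most at 5% of that in control 2 and induced 2; 1 named gene had the opposite pattern. Besides KRT8, KRT19, KRT18, EPCAM and CDH1 of the fibroblast and epithelial list (5 of its 20 genes), the set held H19 (731 and 799 reads), S100A14, AGR2, REG4, TFF2, MUC13 and KRT20. If a single epithelial source had reached both libraries, its genes would stand in 1 ratio between them. The SD of log2(induced 1 / control 1) over the 28 genes was 0.16, where counting error gives 0.20, with a median ratio of 0.07 on the log2 scale. Over all tested genes the SD between these 2 libraries was 1.21, and 0.96 on the log2(RPKM + 1) scale. Those values include the changes between the groups and are no matched reference for the 28 genes. A candidate explanation is RNA, cells or reads of another source added in about equal shares to both libraries; which of these it was stays open, and no biological explanation was tested.

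GADD45G and other induced genes were higher in untreated control 1 than in untreated control 2. The excess was 0.32% of the induced 1 level for GADD45G. Over 9 other induced genes that control 2 nearly lacked (at most 0.3% of an induced 1 level of at least 20 RPKM) the median excess was 0.47%, with 5 genes within 2-fold of GADD45G. The median and these 5 genes lie where carry-over of a fixed share of induced 1 reads or cells into control 1 would put them, within a 2-fold limit. That limit was set after the values were seen and is wider than counting error. CXCL8, 1 of the 5, had an excess of 0.503% with a lower counting bound of 0.484%, above GADD45G. The comparison therefore does not establish carry-over. LIF had an excess of 0.85%, whose lower counting bound of 0.55% lies within 2-fold of GADD45G, CXCL5 had one of 0.15% that rests on 2 reads, and an unnamed locus at 38.5 RPKM in induced 1 was at 0 RPKM in both controls. For PTGS2 the excess was 1.76% (1.31% at the lower end of its counting interval), which a fixed share alone does not give. Expression of the construct without doxycycline stays open as an untested explanation for the GADD45G level in control 1.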
